A study of Mus musculus with 13 samples.

How the data were processed

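RNA abundance was measured by sequencing of total RNA from CD4+ T helper cells of mouse spleen in 13 libraries of 5 groups. Per the labels' protocols, RNA was purified on micro columns, its quality was read on a TapeStation, and libraries were made from 11 ng after depletion of ribosomal RNA. The mice carried either a GFP reporter of Eomes (Eomes-GFP) or the genotype named Eomes-TKO, whose construction the labels do not describe, and both lines also carried a Thy1.1 reporter of Foxp3. Cells were sorted as T cell receptor positive, CD4 positive and Thy1.1 negative, which leaves out cells expressing the Foxp3 reporter. Only the 4-1BB-treated Eomes-GFP animals were divided further, into GFP+ and GFP− fractions.

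The authors deposited 1 table of estimated counts per gene, the unit used throughout. Per the submitters' processing notes, cutadapt 3.4, Trim Galore 0.6.7, STAR 2.7.10a, Salmon 1.5.2 and the GRCm39 build were used. Between 6.25% and 7.33% of the values of a library were not whole numbers, and all were rounded before testing. The table held 56748 genes in 47 library columns. The names of 13 columns matched the labels of 1 sample each, and the other 34 columns were not used here. No coordinates on GRCm39 were used here, and chromosome assignments came from GENCODE M21 on GRCm38, an older build. Total estimated counts ran from 6080975 to 10881146 per library. Levels are given as CPM, counts scaled to a common library size, and 3 counts correspond to 0.271 to 0.468 CPM. Intervals and floors computed from counts cover counting error only. Genes with near-identical copies, among them Eno1 and Gm33707, Ly6c1 and Ly6c2, Ccl3 and Ccl4, and the immunoglobulin and Klra families, are uncertain where reads could be shared between copies.

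Groups were taken from the labels. Each replicate of a group had its own library prefix, and GFP+ and GFP− libraries with the same number shared a prefix, which was read as the animal, giving 10 animals. The labels do not otherwise say that replicates were separate animals, and p-values measure the spread between these libraries. Deviations from the group mean correlated at 0.32, 0.11 and 0.06 within the 3 GFP+ and GFP− pairs sharing a prefix. Pairs not sharing a prefix ran from −0.25 to 0.15, so only the first of the 3 stood apart. Replicate libraries differed beyond counting noise in every group, with a chi-square per degree of freedom between 8.01 and 30.9. No pair therefore differed by counting error alone. Separate libraries made from the same RNA or animal could also differ by more than counting error, so these values cannot exclude such repeats.

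Differences were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the filterByExpr filter, which kept 14059 genes, and the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All 13 libraries entered 1 model with 5 groups and 8 residual degrees of freedom. Every adjusted p of a gene given in the text comes from this model unless another tool is named, and all tests are two-sided. Fold changes are given on the log2 scale with a standard error (SE), taken as the size of the fold change divided by the square root of its F statistic. Levels are given as TMM-scaled CPM with the standard deviation (SD) between libraries. Tests, comparisons, gene lists and the rule for naming genes were fixed before the data were examined. The rule took up to 12 genes per direction with the largest fold change in the 4 main comparisons and up to 5 in the others, among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between libraries, leaving out immunoglobulin and T cell receptor segments and unnamed genes. It added Eomes, Foxp3, Tcf7, Slamf6, Tbx21, Gzmk and Tnfrsf9 in each comparison, and the 10 smallest p-values where fewer than 5 genes passed.

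Of 29 gene lists fixed for T cell programmes and for markers of other cell types, 28 had at least 3 tested members and were compared with all other genes by camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 224 tests of lists and comparisons. Camera with a correlation estimated from the data was run as an alternative. The rotation test fry was also run, and it asks whether a list changed at all, not whether it changed more than other genes. Further alternatives were other normalizations, DESeq2 1.42.0 and limma-voom, other filters, the groups compared alone, the animal or replicate number as a block, a fold threshold of 1.5, and leaving out each library in turn. The test was tried on simulated counts for 14059 genes, with 200 genes averaging at least 4 CPM changed by known folds. In the simulated sort of 4-1BB-treated cells it recovered 66 of 66 genes changed 4-fold, 40 of 67 changed 2-fold and 21 of 67 changed 1.5-fold, with 7 false calls. In the simulated genotype comparison under control antibody it recovered 63 of 66, 50 of 67 and 12 of 67, with 3 false calls, and in the simulated treatment of Eomes-TKO mice 56 of 66, 47 of 67 and 13 of 67, with 6 false calls. These rates do not cover genes at lower levels. With 200 true changes the adjusted threshold is also easier to pass than in comparisons with few calls. It is harder to pass than in the real sort, where 5220 of 14059 genes were called, so the rates for the sort do not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.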

Results

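The transcriptome of CD4+ T helper cells was measured in the spleens of mice bearing Vk12653 multiple myeloma, a transplantable mouse tumour of plasma cells. Mice received an NK1.1-depleting antibody at 50 µg, the tumour cells on day 0, and then 20 µg of either an agonist antibody against 4-1BB, a costimulatory receptor of activated T cells encoded by Tnfrsf9, or a control IgG on days 10, 13 and 16. Spleens were taken on day 18. Eomes is a T-box transcription factor of cytotoxic and memory lymphocytes, and the series asks what it does in progenitor-like helper cells during immunotherapy. Treated Eomes-GFP mice gave 3 GFP+ and 3 GFP− libraries, read from their prefixes as the same 3 animals. Eomes-GFP mice given control IgG gave 2 libraries of cells not divided by GFP. Eomes-TKO mice gave 2 libraries after 4-1BB antibody and 3 after control IgG. Libraries held 6080975 to 10881146 estimated counts and between 17127 and 18252 genes with at least 1 count.

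Eomes itself, the gene altered or reported in these mice, was first checked in each library. It stood at 570, 706 and 685 CPM in the GFP+ libraries and at 3.54, 1.83 and 2.26 CPM in the GFP− libraries. Undivided cells of control-treated Eomes-GFP mice held 14 and 16.8 CPM. Eomes-TKO cells held 3.59 and 8.03 CPM after 4-1BB antibody and 1.36, 2.96 and 3.19 CPM after control IgG, so Eomes reads were low and not absent in the 5 Eomes-TKO libraries. Foxp3, whose reporter was used to exclude regulatory T cells, stayed between 0.393 and 2.65 CPM in all 13 libraries.

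**Figure D1:**
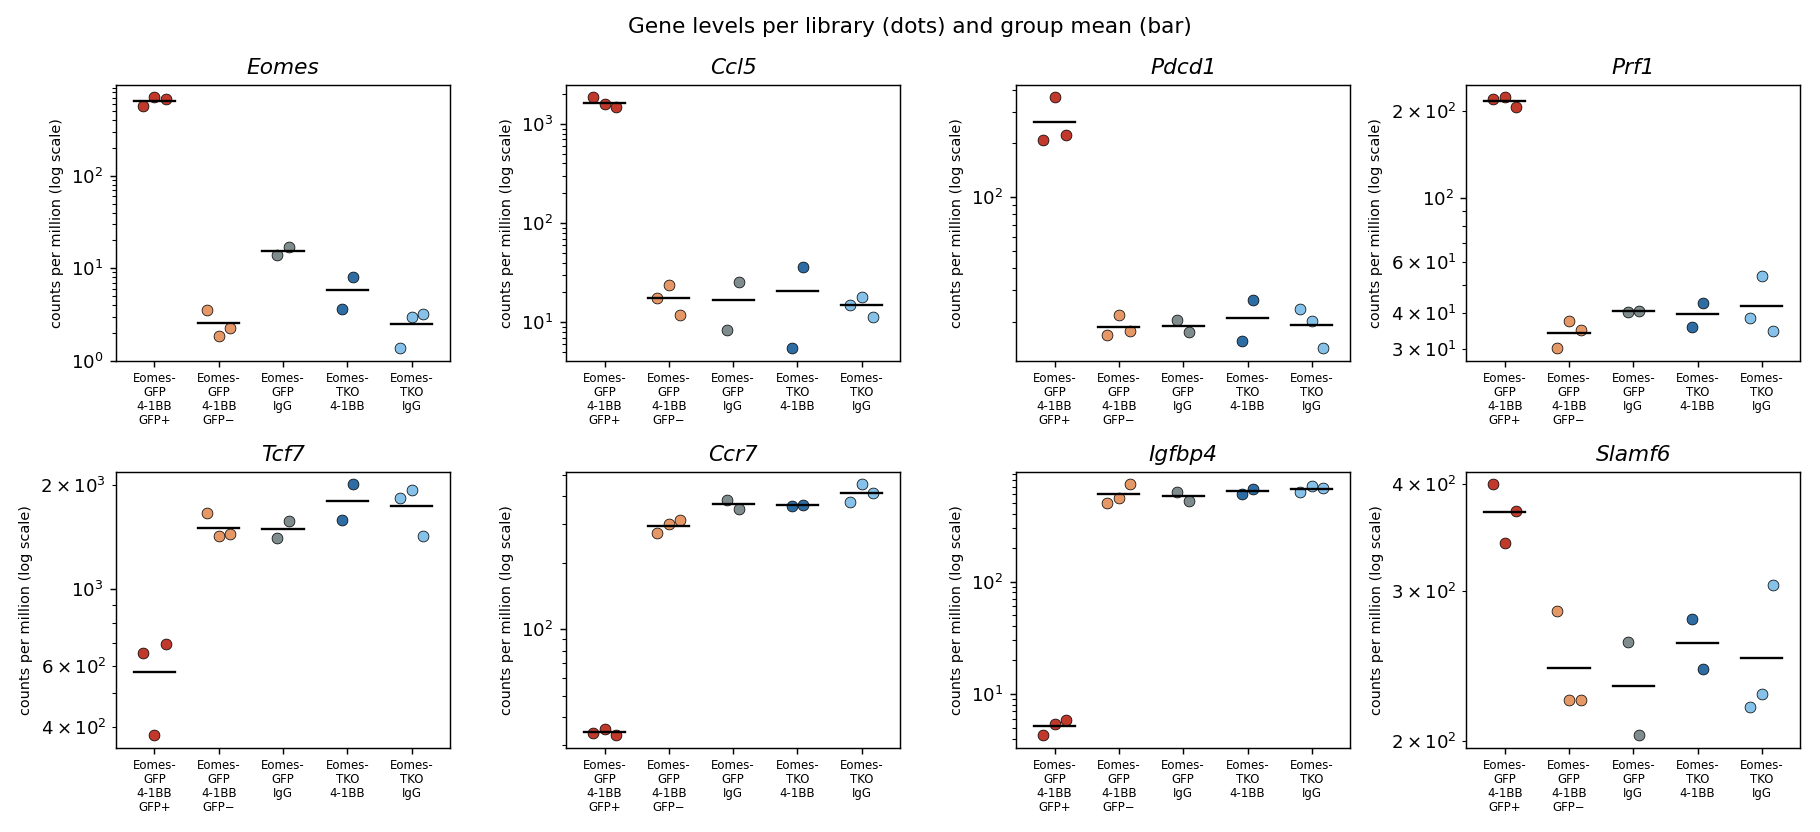
Levels of 8 genes in CPM on a log axis, with each dot 1 library and each bar the group mean, for the 5 groups. The 3 GFP+ libraries stand apart from the other 10 for each gene, with Eomes between 570 and 706 and Tcf7 at 577 ± 172 (SD).

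The first comparison asked how Eomes-expressing helper cells differ from the Eomes-negative helper cells of the same 4-1BB-treated animals. The gates described hold no activation marker, so differences in activation state cannot be told apart from those that go with Eomes. A granzyme and several chemokines were among the genes most raised in GFP+ cells. Gzmk, a granzyme of memory-like effector cells, reached 362 ± 22.9 CPM against 1.40 ± 0.384 CPM (SD, n = 3 and 3; log2 fold change 8.02 ± 0.42 SE, adjusted p = 8.92e-08). Ccl5, an inflammatory chemokine, reached 1640 ± 195 against 17.7 ± 5.86 CPM (log2 fold change 6.54 ± 0.68, adjusted p = 8.52e-05). In the other direction Igfbp4, a gene of naive CD4+ T cells, stood at 5.19 ± 0.821 CPM in GFP+ and 597 ± 123 CPM in GFP− cells (log2 fold change −6.83 ± 0.18, adjusted p = 1.35e-11). Eomes differed by 8.01 ± 0.30 log2 units (adjusted p = 1.87e-09), as the sort on its reporter required.

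In all, 2905 genes were higher and 2315 lower in GFP+ cells, and 1336 and 1150 of these differed by more than 2-fold. Other genes with the largest rises were Gcg, the glucagon precursor, with a log2 fold change of 9.13 ± 0.89, and the chemokines Ccl4 (8.83 ± 0.63) and Ccl3 (8.47 ± 0.69). They also included the receptor tyrosine kinase Ret (8.28 ± 0.37), the adhesion receptor Adgrg1 (7.02 ± 0.42), the inhibitory receptor Havcr2 (6.84 ± 0.57), Pdgfb (6.38 ± 0.44) and Gas7 (6.28 ± 0.35). Gcg reached 213 ± 92.7 CPM and Ret 71.8 ± 11.6 CPM, transcripts with main sites in the gut or pancreas and in neurons. The largest falls after Igfbp4 were Nacc2 (−4.83), Ly6c1 (−4.79), Acvrl1 (−4.75), Dapk1 (−4.67), Cnn3 (−4.20), Amigo2 (−4.05), Treml2 (−4.04), Myo10 (−4.01), Eya2 (−3.89) and Ramp1 (−3.85). Ifngr2, the signalling chain of the interferon-gamma receptor, also fell (−4.06 ± 0.21, 2.93 ± 1.33 against 49.1 ± 1.99 CPM).

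The naive and quiescence list fell most uniformly, with 17 of 18 members lower and none higher, 17 when adjusted over the list alone, and a median log2 fold change of −1.75 (camera adjusted p = 1.8e-14). The list averaged a log2 CPM of 6.16 in GFP+ and 8.56 in GFP− cells, against 8.58 in undivided cells of control-treated Eomes-GFP mice. By this list GFP− cells were thus about as naive as cells not divided by GFP. Il7r, the interleukin-7 receptor, fell by 3.23, Ccr7, which guides cells to lymphoid tissue, fell by 3.11 and Satb1 fell by 3.36. The exception was Klf2, with a log2 fold change of −0.03 ± 0.11. This was the 1 list of the comparison that stayed past the threshold with an estimated correlation (adjusted p = 0.01). The other 11 called lists were lost with an estimated correlation. Fry, which tests a list against no change, passed 11 of the 12, which does not offset that loss where 5220 of 14059 genes were called.

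Cytotoxic genes rose in 17 of 21 members and fell in 1 (18 and 1 adjusted over the list alone; median 2.84, adjusted p = 2.3e-09, and adjusted p = 0.3 with an estimated correlation). Gzmb, the main granzyme of killer cells, changed by 5.35, Nkg7 by 4.95 and Prf1, which encodes perforin, by 2.67, although GFP− cells held Prf1 at 34.1 ± 3.69 and Nkg7 at 28.7 ± 5.21 CPM. Genes chosen beforehand as linked to T-box factors, the T-box list, rose in 13 of 14 (13 adjusted over the list alone, median 2.94, adjusted p = 3.8e-10, adjusted p = 0.28 with an estimated correlation). All of them but Il2rb also stood in other lists, most in the cytotoxic list, so this is not a separate result. Whether they respond to Eomes was not tested. Terminal effector genes rose in 16 of 18 (16 adjusted over the list alone; median 2.12, adjusted p = 3.3e-07, adjusted p = 0.33 with an estimated correlation), among them Klrg1 (5.27 ± 0.54) and Cx3cr1 (4.38 ± 0.42). Th1 genes rose in 9 of 15 and fell in 3, the same counts as when adjusted over the list alone (median 1.43, adjusted p = 0.017, adjusted p = 0.69 with an estimated correlation). Ifng rose by 2.7 ± 0.23, whereas Tbx21, the T-box factor of Th1 cells, was not called at 28.6 ± 11.8 against 23.5 ± 4.06 CPM (log2 fold change 0.28 ± 0.32, adjusted p = 0.53).

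Inhibitory receptors and exhaustion genes rose in 16 of 20 and fell in 2 (16 and 2 adjusted over the list alone; median 2.77, adjusted p = 1e-07, adjusted p = 0.33 with an estimated correlation). Tigit rose by 5.09 ± 0.54, the ectonucleotidase Entpd1 by 4.92 ± 0.23, Lag3 by 4.84 ± 0.64, Pdcd1, which encodes PD-1, by 3.82 ± 0.27 and the exhaustion-linked factor Tox by 2.43 ± 0.10. Nr4a2 rose by 3.19 while Nr4a1 fell by 1.21. Genes of interleukin-10-producing type 1 regulatory cells rose in 11 of 16 and fell in 1 (11 and 2 adjusted over the list alone; median 2.26, adjusted p = 0.00057, adjusted p = 0.48 with an estimated correlation). Il10 rose by 6.47 ± 0.59 to 23.9 ± 7.32 CPM, Prdm1, which encodes Blimp-1, by 3.50 ± 0.19 and Maf by 2.50 ± 0.27.

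The progenitor list, which bears on the series' title, was split. Of its 18 members 7 rose and 8 fell, the same counts as when adjusted over the list alone. Camera did not call the list (median 0.13, mean 0, test direction down, adjusted p = 0.6, adjusted p = 0.76 with an estimated correlation), whereas fry, against no change, called it lower (adjusted p = 4e-04, and 2.8e-05 for GFP+ cells against control IgG). Tcf7, which encodes the stem-like factor TCF1, fell by 1.38 ± 0.20 to 577 ± 172 CPM from 1510 ± 130 CPM (adjusted p = 0.000137). Lef1 (−1.46 ± 0.15), Bach2 (−1.75 ± 0.16), Il7r and Ccr7 fell as well. Slamf6, a surface receptor of progenitor cells, rose by 0.61 ± 0.14 (371 ± 29.3 against 244 ± 34.8 CPM, adjusted p = 0.00408; adjusted p = 0.631 against a fold threshold of 1.5). Cxcr5 (4.08 ± 0.30), Xcl1 (3.41 ± 0.60), Myb (2.49 ± 0.13), Cxcr3 (1.43 ± 0.31), Cd28 (0.83 ± 0.10) and Cd27 (0.69 ± 0.12) also rose.

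Proliferation genes rose in 31 of 33 (32 adjusted over the list alone; median 1.56, adjusted p = 1.5e-10, adjusted p = 0.47 with an estimated correlation), with Mki67 at 584 ± 125 against 202 ± 44.7 CPM and Hmmr up by 1.74 ± 0.27. Pcna (0.17) and Ube2c (1.3, adjusted p = 0.053) were not called. Apoptosis and survival genes rose in 12 of 20 and fell in 2 (13 and 2 adjusted over the list alone; median 0.66, adjusted p = 0.0031, adjusted p = 0.41 with an estimated correlation). Interferon response genes fell in 11 of 30 and rose in 3 (12 and 3 adjusted over the list alone; median −0.52, adjusted p = 0.0098, adjusted p = 0.76 with an estimated correlation and 0.1 by fry). Immediate early genes fell in 11 of 23 and rose in 2 (the same counts adjusted over the list alone; median −0.42, adjusted p = 0.018, adjusted p = 0.55 with an estimated correlation; adjusted p = 0.051 without GFP+ replicate 1). Th17 genes fell in 5 of 7 and rose in 1 (the same counts adjusted over the list alone; median −2.24, adjusted p = 0.027, adjusted p = 0.43 with an estimated correlation). Jun fell by 1.78 on the log2 scale. Tnfrsf9, the target of the antibody, rose by 2.64 ± 0.26 to 57.3 ± 12 CPM from 9.28 ± 2.76 CPM. Foxp3 was lower in GFP+ cells at 0.495 ± 0.0888 against 1.44 ± 0.453 CPM (log2 fold change −1.50, adjusted p = 0.0432). This call was lost with the animal as a block (−1.48, adjusted p = 0.06) and when any of the 6 libraries was left out (adjusted p between 0.0503 without GFP− replicate 2 and 0.148 without GFP− replicate 1).

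Lists of markers of other cells were not called by camera, while fry, against no change, called the myeloid (adjusted p = 0.046) and plasma cell (0.04) lists higher and the B cell (0.027) and innate-like T cell (0.018) lists lower. The plasma cell and myeloma list had 3 of 8 members higher and 2 lower, also when adjusted over the list alone (median 0.59, camera adjusted p = 0.62), and a mean log2 CPM of 4.35 against 3.4. Myeloid markers rose in 2 of 10 (2 adjusted over the list alone; median 0.52, adjusted p = 0.24), namely Cd68 (2.17 ± 0.23, 23.4 ± 3.56 against 5.18 ± 0.716 CPM) and Itgam (1.46 ± 0.24), both also found in effector lymphocytes. Lyz2 was at 13.7 ± 7.76 against 9 ± 4.23 CPM without a call. Of the innate-like T cell markers, Zbtb16, which encodes PLZF, was at −4.24 ± 0.52 and Klrb1c, which encodes the depleted NK1.1, at −1.53 ± 0.47 (2 of 9 higher and 4 lower; list adjusted p = 0.26). Igkc, the immunoglobulin kappa constant region, rose by 7.85 ± 0.67 to 79.2 ± 2.96 CPM from 0.355 ± 0.229 CPM, a gene outside the naming rule that was chosen after its values were seen. The B cell list held no higher member and 1 lower member of 4, Cd79a at 0.236 ± 0.218 against 1.21 ± 0.519 CPM. The higher share of the called genes depended on the scaling: TMM gave 55.7% higher and upper-quartile normalization 41.4% (2186 higher and 3095 lower), with a median shift over all genes of −0.116.

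**Figure D2:**
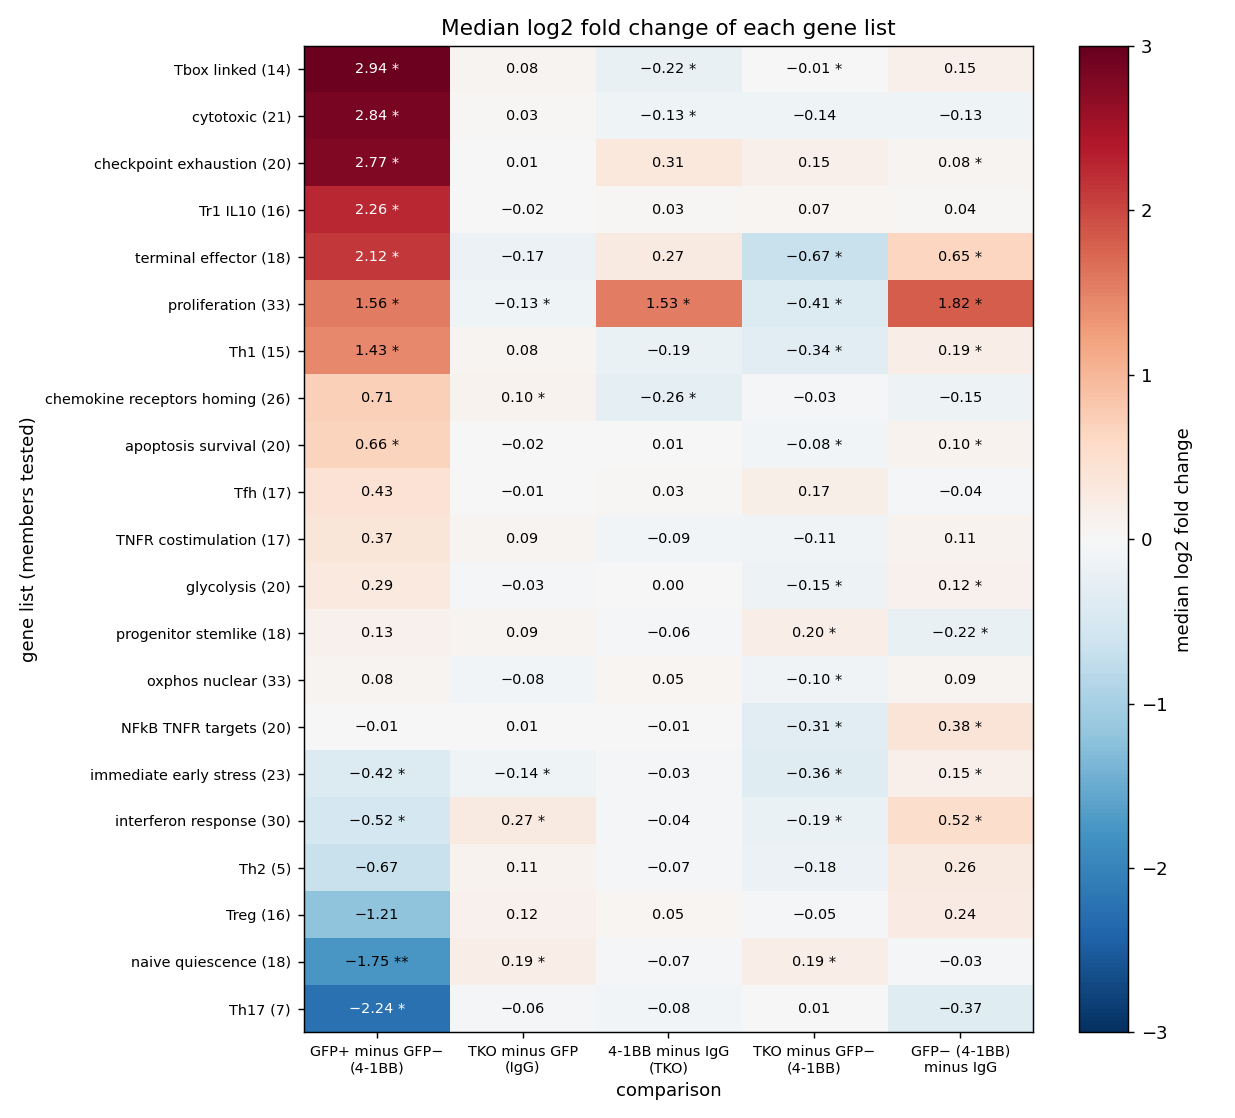
Median log2 fold change of each gene list (vertical axis, members tested in brackets) in 5 comparisons (horizontal axis). A star marks an adjusted p of at most 0.05 by camera with the preset correlation, and a pair of stars marks a list that also passed with an estimated correlation, which was the naive list at −1.75 alone.

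The Eomes-TKO genotype was next compared with Eomes-GFP under control IgG, in cells not divided by Eomes. Few genes were called. Undivided Eomes-GFP control cells averaged 15.4 CPM of Eomes, against 654 CPM in treated GFP+ cells. A difference confined to Eomes-expressing cells could therefore be diluted below detection. Genotype and any batch of the animals cannot be told apart in this comparison. Eomes was lower in Eomes-TKO cells, at 2.50 ± 0.998 CPM against 15.4 ± 2.01 CPM (SD, n = 3 and 2; log2 fold change −2.64 ± 0.33 SE, adjusted p = 0.0219). Kcnc1, which encodes a voltage-gated potassium channel, was at 0.558 ± 0.127 against 4.07 ± 0.895 CPM (log2 fold change −2.86 ± 0.33, adjusted p = 0.00696). These 2 genes were the only ones called by edgeR, against 430 genes with an unadjusted p under 0.05, and DESeq2 called 5 and limma-voom 6.

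The next smallest p-values belonged to genes that did not pass the threshold. Myb, a factor of progenitor lymphocytes, stood at 42.3 ± 2.72 against 72.9 ± 4.50 CPM (log2 fold change −0.79 ± 0.14, adjusted p = 0.2) and Stt3b, an oligosaccharyltransferase subunit, at 311 ± 17.4 against 188 ± 29.1 CPM (0.73 ± 0.14, adjusted p = 0.398). Gm33707 was at 12.2 ± 6.39 CPM and had no counts in the Eomes-GFP libraries, a difference of at least 73.7-fold against a floor of 3 counts over the group. Ptprm at 1.05 ± 0.042 CPM and Zc3h12c at 0.959 ± 0.802 CPM in Eomes-GFP cells had no counts in the Eomes-TKO libraries, at least 9.52-fold and 8.71-fold lower. Ide (0.56) and the chaperones Dnaja1 (−0.61) and Hsp90aa1 (−0.56) followed. Tcf7 differed by 0.22 ± 0.22, Slamf6 by 0.11 ± 0.16, Tbx21 by 0.18 ± 0.37, Tnfrsf9 by −0.07 ± 0.28, Foxp3 by 0.78 ± 0.56 and Gzmk by −0.84 ± 1.1, each with an adjusted p of 1.

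Among the lists, 28 of 30 interferon response genes had a positive fold change in Eomes-TKO cells (median 0.27, adjusted p = 1.1e-05, adjusted p = 0.61 with an estimated correlation). So had 16 of 18 naive and quiescence genes (median 0.19, adjusted p = 0.0014, adjusted p = 0.28 with an estimated correlation). The proliferation list (median −0.13, adjusted p = 0.0024, adjusted p = 0.75 with an estimated correlation) and the immediate early list (median −0.14, adjusted p = 0.0077, adjusted p = 0.48 with an estimated correlation) were lower. The homing receptor list was higher (median 0.10, adjusted p = 0.028, adjusted p = 0.69 with an estimated correlation). No member of these lists was called over all genes tested. Adjusted over the list alone the naive, immediate early and homing lists held 1 called gene each. The Eomes call was lost without replicate 1 or 2 of the Eomes-GFP control group (adjusted p = 0.0695 and 0.344) or replicate 1 or 2 of the Eomes-TKO control group (0.0554 and 0.17). The Kcnc1 call was lost without the last 3 of these (0.304, 0.0554 and 0.0616). With the 2 groups fitted alone, Eomes (adjusted p = 0.0634) and Kcnc1 (0.156) were both lost and Slfn8 was called instead. No gene was called without replicate 2 of the Eomes-GFP control group or without replicate 1 or 2 of the Eomes-TKO control group (298, 454 and 358 genes with an unadjusted p under 0.05). Without replicate 3 of the latter, 5 were called. Among the lists, the interferon call was lost without Eomes-TKO replicate 2 (adjusted p = 0.26), the proliferation call without Eomes-GFP replicate 2 (0.7) or Eomes-TKO replicate 3 (0.15). The immediate early call was lost without Eomes-GFP replicate 1 (0.19) or Eomes-TKO replicate 3 (0.32), and the homing call without Eomes-GFP replicate 1 (0.71) or Eomes-TKO replicate 2 or 3 (0.2 and 0.13).

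The response to 4-1BB antibody in Eomes-TKO mice was compared with control IgG in the same genotype. Cell division genes were higher after 4-1BB antibody. Nusap1, a spindle protein, rose from 2.27 ± 0.295 to 11.6 ± 4.77 CPM (SD, n = 3 and 2; log2 fold change 2.37 ± 0.29 SE, adjusted p = 0.0134) and the spindle pole gene Aspm from 5.02 ± 0.872 to 14.6 ± 5.17 CPM (1.56 ± 0.24, adjusted p = 0.0388). Hmmr (2.53 ± 0.36), Spag5 (2.36 ± 0.32), Ckap2 (1.97 ± 0.31) and Cdca8 (1.83 ± 0.29), all mitotic genes, also rose and were named outside the rule after their values were seen. These 6 genes were the whole set of calls, none was lower, and 506 genes had an unadjusted p under 0.05.

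All 33 proliferation genes had a positive fold change, 2 of them called over all genes and 26 adjusted over the list alone (median 1.53, adjusted p = 4e-37, adjusted p = 0.24 with an estimated correlation). Mki67 was at 65.4 and 190 CPM after 4-1BB antibody against 31.8, 43.9 and 24.7 CPM after control IgG. The homing receptor list was lower (median −0.26, adjusted p = 2.2e-06, adjusted p = 0.33 with an estimated correlation). Markers of other cells moved with the same treatment. The myeloid list was higher (median 1.26, adjusted p = 0.036, adjusted p = 0.48 with an estimated correlation), with Lyz2 at 5.11 ± 1.04 against 0.688 ± 0.676 CPM. The plasma cell and myeloma list was higher (median 0.18, mean 1.64, adjusted p = 0.0051, adjusted p = 0.3 with an estimated correlation), with Igkc at 11.5 ± 5.87 against 0.589 ± 0.936 CPM and Jchain at 3.96 ± 1.03 CPM against no counts. Of the myeloid list 1 gene, and of the plasma cell list 2, were called when adjusted over the list alone. The cytotoxic list (median −0.13, mean 0.09, adjusted p = 0.036, adjusted p = 0.7 with an estimated correlation) and the T-box list (median −0.22, mean 0.12, adjusted p = 0.042, adjusted p = 0.7 with an estimated correlation) were called lower against a positive mean. Their members overlap, so the lists are not separate results. Both turned to the other direction without replicate 1 of the treated group (adjusted p = 0.078 and 0.062). The innate-like T cell list was lower (median −0.08, adjusted p = 0.047, adjusted p = 0.41 with an estimated correlation), with Klrb1c at 4.01 ± 0.373 against 9.52 ± 3.26 CPM. The homing call was lost without treated replicate 1 (adjusted p = 0.56), the myeloid call without treated replicate 2 (0.42) or control replicate 1 or 2 (0.094 and 0.078), and the plasma cell call without treated replicate 2 (0.11) or control replicate 3 (0.09). The cytotoxic and T-box calls were lost without control replicate 2 (0.33 and 0.4), and the innate-like call without treated replicate 1 or 2 (0.24 and 0.14) or control replicate 2 or 3 (0.26 and 0.062).

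None of the 7 genes followed in each comparison was called in this one. Eomes differed by 1.29 ± 0.37 (adjusted p = 0.674; 0.0453 without replicate 1 of the treated group), Gzmk by 2.99 ± 0.79 (adjusted p = 0.566), Tcf7 by 0.05 ± 0.22, Slamf6 by 0.06 ± 0.16, Tbx21 by −0.36 ± 0.37, Tnfrsf9 by −0.10 ± 0.29 and Foxp3 by 0.53 ± 0.52. The genes that were higher and lower in GFP+ cells of treated Eomes-GFP mice, tested as sets, were not called in this comparison (adjusted p = 0.94 and 0.91) nor in the genotype comparison under control IgG (adjusted p = 0.91 for both). The treated Eomes-TKO libraries differed between themselves. The set higher in GFP+ cells was called higher without treated replicate 1 (adjusted p = 0.00014) and lower without treated replicate 2 (0.00071). The set lower in GFP+ cells was called lower without treated replicate 1 (0.011). Leaving out treated replicate 1 gave 83 calls, leaving out treated replicate 2 gave 0, and leaving out replicates 1, 2 and 3 of the control group gave 1, 0 and 4 calls. The Nusap1 call was lost without treated replicate 2 (adjusted p = 0.269) or control replicate 1 or 2 (0.0502 and 0.0955), and the Aspm call without treated replicate 2 (0.716) or any control replicate (0.19, 0.1 and 0.0578). With no call, 933 genes (without treated replicate 2) and 482 genes (without control replicate 2) had an unadjusted p under 0.05. With all libraries DESeq2 called 59 genes and limma-voom 0.

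**Figure D3:**
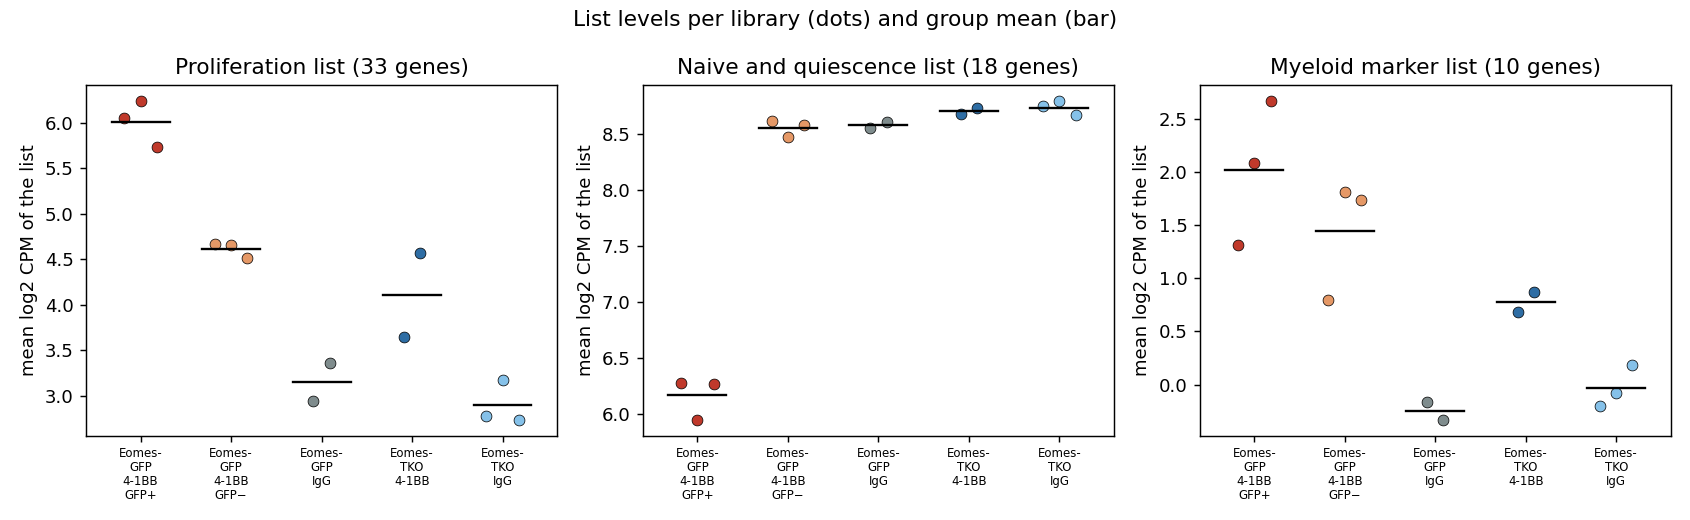
Mean log2 CPM of the proliferation, naive and myeloid marker lists in each library (dots) with the group mean (bar), for the 5 groups. Proliferation averaged 4.61 in GFP− and 4.11 in Eomes-TKO cells after 4-1BB antibody against 3.15 and 2.90 after control IgG, and the myeloid markers moved in the same libraries from −0.24 and −0.03 to 1.45 and 0.77.

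GFP− cells of treated Eomes-GFP mice were then compared with undivided cells of Eomes-GFP mice given control IgG, which measures treatment in cells without Eomes together with the removal of GFP+ cells by the sort. Cyclin B1, encoded by Ccnb1, rose from 1.65 ± 0.713 to 11.4 ± 1.09 CPM (SD, n = 2 and 3; log2 fold change 2.75 ± 0.45 SE, adjusted p = 0.0204). Pclaf (2.28 ± 0.43), Ccnb2 (2.21 ± 0.44), Ccna2 (2.18 ± 0.40) and Stil (2.16 ± 0.45) rose with it, all genes of DNA replication or mitosis. Eomes fell by 2.61 from 15.4 ± 2.01 to 2.54 ± 0.889 CPM (adjusted p = 0.00589), and Myb fell by 1.1 from 72.9 ± 4.50 to 34.0 ± 3.96 CPM (adjusted p = 0.00372). Zfp719 (−0.95 ± 0.20), Clec2d, a ligand of NK receptors (−0.89 ± 0.17), and Alg11 (−0.68 ± 0.13) were the next lower genes.

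Altogether 92 genes were higher and 15 lower, with 1231 genes at an unadjusted p under 0.05. Proliferation genes rose in 14 of 33 (28 adjusted over the list alone; median 1.82, adjusted p = 1e-35, adjusted p = 0.24 with an estimated correlation). Targets of NF-kB and tumour necrosis factor receptors rose in 2 of 20 (9 adjusted over the list alone; median 0.38, adjusted p = 8.7e-08, adjusted p = 0.27 with an estimated correlation), led by Tnfaip3, a feedback inhibitor of NF-kB (1.65 ± 0.21, adjusted p = 0.00372). All 30 interferon response genes had a positive fold change, 0 of them called over all genes by edgeR and 3 adjusted over the list alone (median 0.52, adjusted p = 5.1e-09, adjusted p = 0.47 with an estimated correlation). In treated against control Eomes-TKO cells, which share 1 gate, camera called neither list. The NF-kB list had a median of −0.01 there (adjusted p = 0.87) and the interferon list −0.04 (adjusted p = 0.97). A response to the antibody cannot be told apart from the change of gate in GFP− cells. The terminal effector (median 0.65, adjusted p = 0.00022, adjusted p = 0.47 with an estimated correlation) and Th1 lists (median 0.19, adjusted p = 0.015, adjusted p = 0.69 with an estimated correlation) were higher with 1 called member each, 2 and 3 adjusted over the list alone. The progenitor list was lower (median −0.22, adjusted p = 0.0052, adjusted p = 0.24 with an estimated correlation) with Myb as its 1 called member, also when adjusted over the list alone. Tcf7 (0.02 ± 0.22) and Slamf6 (0.07 ± 0.16) were not called. Nr4a1, an early target of antigen receptor signalling, rose by 0.86 ± 0.12.

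Myeloid markers were higher in the same libraries (10 of 10 positive, 1 called and 3 adjusted over the list alone; median 2.16, adjusted p = 1.4e-06, adjusted p = 0.24 with an estimated correlation), with Lyz2, a macrophage and neutrophil lysozyme, at 9 ± 4.23 against 0.352 ± 0.221 CPM (log2 fold change 4.69 ± 0.87, adjusted p = 0.0299). Gamma delta T cell markers were lower (0 of 7 positive, 0 called over all genes by edgeR or adjusted over the list alone, median −1.11, adjusted p = 0.048, adjusted p = 0.47 with an estimated correlation), a call lost without GFP− replicate 3 (0.25) or control replicate 2 (0.49). Of the other followed genes, Tbx21 differed by 0.47 ± 0.37, Tnfrsf9 by −0.68 ± 0.29, Foxp3 by 0.63 ± 0.56 and Gzmk by 1.04 ± 0.84, none called. The count depended on single libraries. It was 16, 21 and 21 without GFP− replicate 1, 2 or 3, 14 without control replicate 1 and 1 without control replicate 2, where the Eomes and Myb calls were lost (adjusted p = 0.084 for both). The calls of the other 8 genes named by the rule were lost with any 1 of the 5 libraries left out (adjusted p between 0.054 and 0.458). The terminal effector call was lost without control replicate 1 (0.29), and the Th1 call without GFP− replicate 2 (0.21) or control replicate 1 (0.38).

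Treated Eomes-TKO cells were compared with treated GFP− cells, both low in Eomes. The gates differed, since Eomes-TKO cells were not divided by GFP. Genotype, gate and any batch of the animals therefore cannot be told apart in this comparison. Called genes were few, and 5 were lower in Eomes-TKO cells. Tnfaip3 was at 533 ± 128 against 1330 ± 127 CPM (SD, n = 2 and 3; log2 fold change −1.32 ± 0.20 SE), the nuclear receptor Nr4a2 at 7.11 ± 0.119 against 16.2 ± 1.01 CPM (−1.19 ± 0.19) and the phosphatase Dusp5 at 56.9 ± 2.79 against 120.0 ± 22.8 CPM (−1.07 ± 0.16). Rgs1, a regulator of G protein signalling, was at 35.2 ± 6.01 against 73.5 ± 2.82 CPM (−1.06 ± 0.14) and the clock gene Per1 at 118 ± 13.6 against 226 ± 16.0 CPM (−0.94 ± 0.14). Each had an adjusted p of 0.038. Gm33707, outside the naming rule, was the 1 higher gene, at 15.4 CPM against no counts, at least 141-fold.

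The NF-kB target list was lower (1 of 20 called, 7 adjusted over the list alone; median −0.31, adjusted p = 1.4e-08, adjusted p = 0.24 with an estimated correlation). So were the immediate early list (0 of 23 called by edgeR, 6 adjusted over the list alone; median −0.36, adjusted p = 1.1e-07, adjusted p = 0.28 with an estimated correlation) and the proliferation list, with 32 of 33 genes negative (0 called over all genes or adjusted over the list alone; median −0.41, adjusted p = 4.6e-09, adjusted p = 0.51 with an estimated correlation). The terminal effector (median −0.67, adjusted p = 2.8e-05, adjusted p = 0.46 with an estimated correlation) and Th1 lists (median −0.34, adjusted p = 3e-05, adjusted p = 0.47 with an estimated correlation) were lower too, with 2 genes each adjusted over the list alone. The progenitor list was higher, with 17 of 18 genes positive (median 0.20, adjusted p = 0.0052, adjusted p = 0.24 with an estimated correlation). The naive list was higher too, with 16 of 18 (median 0.19, adjusted p = 0.0054, adjusted p = 0.3 with an estimated correlation). No member of these last lists was called, also when adjusted over the list alone. Tcf7 differed by 0.25 ± 0.22, Slamf6 by 0.10 ± 0.16, Tbx21 by −0.65 ± 0.37, Tnfrsf9 by 0.51 ± 0.29, Eomes by 1.26 ± 0.37, Foxp3 by 0.68 ± 0.52 and Gzmk by 1.11 ± 0.62, none called. Myeloid markers were lower (median −0.43, adjusted p = 0.039, adjusted p = 0.5 with an estimated correlation).

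The 6 calls of this comparison were not stable. With upper-quartile normalization 0 genes passed in edgeR, and 980 genes had an unadjusted p under 0.05 with TMM. DESeq2 called 52 genes and limma-voom 3. Leaving out GFP− replicate 1, 2 or 3 gave 0, 1 and 0 calls (896, 637 and 771 genes at an unadjusted p under 0.05). Leaving out Eomes-TKO replicate 1 or 2 gave 9 and 15. Each of the 5 lower genes lost its call without at least 4 of the 5 libraries (adjusted p between 0.0732 and 0.176). Without Eomes-TKO replicate 1 the proliferation, terminal effector and Th1 lists were not called (adjusted p = 0.77, 0.35 and 0.36), without Eomes-TKO replicate 2 the progenitor and naive lists were not (0.26 and 0.1). The myeloid call was lost without GFP− replicate 2 or 3 (0.31 and 0.11) or Eomes-TKO replicate 1 or 2 (0.33 and 0.053). The NF-kB and immediate early calls held in each case.

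GFP+ cells were also compared with treated Eomes-TKO cells and with undivided cells of control-treated Eomes-GFP mice. Neither of these was divided by GFP, so each difference includes the sort on GFP. Against treated Eomes-TKO cells, 2645 genes were higher and 2214 lower in GFP+ cells. Gzmk stood at 2.66 ± 3.32 CPM in Eomes-TKO cells (SD, n = 2) against 362 ± 22.9 CPM in GFP+ cells (SD, n = 3), a log2 fold change of −6.91 ± 0.47 SE for Eomes-TKO minus GFP+. Ccl4 was at −7.54 ± 0.68 and Ier3 at −7.27 ± 0.62, and Enpp6 and Ret were at 0.0781 and 0.182 CPM against 29.3 and 71.8 CPM. Igfbp4 (6.93 ± 0.19), Acvrl1 (4.86 ± 0.21), Ly6c1 (4.83 ± 0.40), Cnn3 (4.35 ± 0.22) and Ifngr2 (4.28 ± 0.22) were the most raised in Eomes-TKO cells. Tcf7 was higher in Eomes-TKO cells by 1.64 ± 0.22 (adjusted p = 7.28e-05) and Foxp3 by 2.18 ± 0.58 (adjusted p = 0.00883; 0.0601 without Eomes-TKO replicate 1). Slamf6 (−0.51 ± 0.16, adjusted p = 0.0243; 0.0809 and 0.063 without GFP+ replicate 1 or 3, 0.0549 and 0.142 without Eomes-TKO replicate 1 or 2, 0.131 with upper-quartile normalization), Tnfrsf9 (−2.13 ± 0.29) and Eomes (−6.75 ± 0.33) were lower, and Tbx21 (−0.93 ± 0.37, adjusted p = 0.0741) was not called. Myeloid markers were lower in Eomes-TKO cells (0 of 10 positive, 2 called over all genes and adjusted over the list alone, median −1.48, adjusted p = 0.042, adjusted p = 0.5 with an estimated correlation). That call was lost without GFP+ replicate 2 or 3 (0.051 and 0.055) or Eomes-TKO replicate 1 (0.082). Without Eomes-TKO replicate 1 the count of 4859 genes was 3060. The scaling moved the split, from 45.6% higher in Eomes-TKO cells with TMM to 60.8% with upper-quartile normalization (3126 higher and 2019 lower; median shift 0.162).

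Against undivided cells of control-treated Eomes-GFP mice, 2642 genes were higher and 2167 lower in GFP+ cells. Ccl3 rose by 9.71 ± 0.94, Gzmk by 9.06 ± 0.56 and Gcg by 8.87 ± 1.05. Ret was at 71.8 ± 11.6 CPM against 0.147 ± 0.208 CPM, and Enpp6, at 29.3 ± 1.90 CPM, was at least 177-fold higher than in the control libraries, which had no counts (floor of 3 counts over the group). Igfbp4 (−6.77 ± 0.19), Acvrl1 (−4.93 ± 0.21), Ly6c1 (−4.65 ± 0.40), Cnn3 (−4.62 ± 0.21) and Myo10 (−4.30 ± 0.24) were the most lowered. Eomes rose by 5.40 ± 0.30, Tnfrsf9 by 1.96 ± 0.29 and Slamf6 by 0.68 ± 0.16 (adjusted p = 0.00489; 0.0898 without control replicate 2). Tcf7 fell by 1.37 (adjusted p = 0.000292), and Tbx21 (0.76 ± 0.37) and Foxp3 (−0.87 ± 0.62) were not called. Myeloid markers rose in 5 of 10 members (9 adjusted over the list alone), with 10 of 10 positive (median 2.67, adjusted p = 0.0011, adjusted p = 0.32 with an estimated correlation). The count of 4809 genes was 3195 without replicate 1 of the control group. TMM gave 54.9% higher and upper-quartile normalization 41.9% (2130 higher and 2950 lower; median shift −0.138).

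T cell receptor usage was summarised by the evenness of beta chain V gene counts, the inverse Simpson index, in which lower values mean that fewer V genes hold more of the counts. GFP+ cells had an index of 12.7 ± 0.3 (SD, n = 3) and GFP− cells 14.8 ± 0.4 (SD, n = 3), a difference of −2 with an exact permutation p of 0.1 over the 6 libraries taken as unpaired. Sign flips within the 3 animals gave an exact permutation p of 0.25. Each is the smallest its permutations can give. The other groups lay at 15.3 ± 0.1, 15.2 ± 0 and 15 ± 0.2. Alpha chain V genes gave 34.3 ± 7.2 in GFP+ and 51.9 ± 0.3 in GFP− cells (exact permutation p = 0.1, and 0.25 within animals), with a difference of −17.5.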

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

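The interaction of genotype and treatment and the divisions of the sorted libraries were planned, and the repeat of the interaction with GFP− cells alone was chosen after the planned result was seen.

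A test of the interaction itself called 516 genes, with the mean of GFP+ and GFP− cells at equal weight standing for treated Eomes-GFP mice. The other arms were not divided by GFP, so these calls mix the sort on GFP with any difference in response. GFP+ and GFP− libraries of the same animal were treated as independent. By this measure the response was higher in Eomes-TKO mice for 248 genes, with the largest log2 differences for Pdlim4 (3.45 ± 0.37 SE), Chdh (3.44 ± 0.44), Igfbp4 (3.28 ± 0.20), Il9r (2.88 ± 0.49) and Ampd1 (2.71 ± 0.41). It was lower for 268 genes, with the largest differences for the cytotoxic genes Gzmb (−3.98 ± 0.87) and Nkg7 (−3.47 ± 0.68), the chemokine receptor Cx3cr1 (−3.47 ± 0.76), the signalling adaptor Pik3ap1 (−3.27 ± 0.62) and Hip1 (−3.09 ± 0.63). Naive and quiescence genes differed upwards with a median of 1 (13 of 18 called, 15 adjusted over the list alone, adjusted p = 0.01 with an estimated correlation). Myeloid markers differed downwards in the same test (1 of 10 positive, 1 called over all genes and adjusted over the list alone, median −1.88, adjusted p = 0.0082, adjusted p = 0.41 with an estimated correlation). DESeq2 called 733 genes and limma-voom 488, without Gzmb (adjusted p = 0.191) and Pik3ap1 (0.093).

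Equal weight counts GFP+ cells as strongly as GFP− cells, and the share of GFP+ cells in the spleen was not used here. With GFP− cells alone standing for treated Eomes-GFP mice, 0 genes were called by edgeR, the 1 tool run on it, with 416 genes at an unadjusted p under 0.05 and Eomes at the smallest adjusted p (0.0621; log2 difference 3.90). The planned count was 199 and 222 without Eomes-GFP control replicate 1 or 2, 244 without treated Eomes-TKO replicate 1, and 331 and 343 without control Eomes-TKO replicate 1 or 2. Without Eomes-GFP control replicate 1, Gzmb, Nkg7, Hip1 and Pik3ap1 lost their calls (adjusted p = 0.138, 0.133, 0.126 and 0.0602), and the first 3 also without control replicate 2 (0.0861, 0.0835 and 0.0776). Cx3cr1 lost its call without treated Eomes-TKO replicate 1 or 2 (0.165 and 0.0832). Gzmb was also lost without GFP− replicate 1 (0.0525), treated Eomes-TKO replicate 1 (0.0603) or control Eomes-TKO replicate 1 or 2 (0.0631 and 0.105), and Nkg7 without control Eomes-TKO replicate 2 or 3 (0.0637 and 0.0526). Hip1 was lost without any control Eomes-TKO replicate (0.0592, 0.056 and 0.0597), and Cx3cr1 without GFP+ replicate 1 (0.0502), GFP− replicate 2 or 3 (0.0531 and 0.0509) or control Eomes-TKO replicate 3 (0.0541). The other 5 genes named held in each case.

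For the sort of treated cells, the 6 libraries divide into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 5220 genes, the highest of the others 0, and 1 of the 10 reached the real count. The other divisions that part each pair of libraries from 1 animal also called 0. Every division but the real one mixes GFP+ and GFP− libraries in both arms. The sort difference then enters the spread and leaves few calls, so these counts do not measure chance.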

How the results depend on the processing

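The repeat of the interaction with GFP− cells alone, the sets of the 200 largest genes and the sign flips of V gene evenness within animals (difference −2, exact permutation p = 0.25) were chosen after the results were seen, and all other alternatives were planned. In the text below the comparisons are the sort of treated cells, genotype under control IgG, treatment of Eomes-TKO mice, treated Eomes-TKO against GFP− and against GFP+ cells, GFP+ and GFP− cells against control IgG, and the interaction, and the cause of each change was not tested unless given. For genes and lists named in the text, beside the values given below, 881 values kept direction and side of the threshold under other settings and 124 lost the call; with 1 library left out, 602 kept both, 152 lost the call and 4 lists turned.

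For the sort, the counts moved by less than 1.5 times under other normalizations, tools, filters and blocks. A fold threshold of 1.5, a stricter hypothesis by construction, gave 2146 genes, and gave 1 for genotype, 0 for treatment, 0 for Eomes-TKO against GFP−, 2153 for Eomes-TKO against GFP+, 2214 for GFP+ and 3 for GFP− against control IgG, and 129 for the interaction. DESeq2's Wald test gave 5 genes for genotype, 59 for treatment, 52 for Eomes-TKO against GFP− and 282 for GFP− against control IgG, and limma-voom 6, 0, 3 and 237 for the same comparisons. Without a filter, when 23638 genes were tested, the counts were 112, 258, 220 and 521, and 1054 for the interaction. The groups compared alone gave 1 gene for genotype, which was neither Eomes nor Kcnc1, 0 for treatment and 393 for GFP− against control IgG. Upper-quartile normalization gave 10 for treatment and 0 for Eomes-TKO against GFP−. With GFP− cells alone as the treated arm the interaction held 0 genes.

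With the replicate number as a block the counts were 15 for treatment, 12 for Eomes-TKO against GFP− and 266 for GFP− against control IgG, although the number pairs libraries by animal in the sort alone. With the animal as a block, Foxp3 in the sort had a log2 fold change of −1.48 and lost its call, and no other call of the sort named here changed. Under that block the sort held 5157 genes, and 5514 with its 6 libraries alone.

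An estimated correlation left 1 called list in the sort, 0 in genotype, 0 in treatment, 0 in Eomes-TKO against GFP−, 1 against GFP+, 1 in GFP+ and 0 in GFP− against control IgG, and 1 in the interaction. Fry, which tests against no change, kept 11 of the 12 called lists in the sort and left 0 lists in genotype, 2 in treatment, 3 in Eomes-TKO against GFP− and 4 in GFP− against control IgG. The set of genes higher in GFP+ cells, not called in the genotype comparison, turned direction there with fry (adjusted p = 1), with its 200 largest genes (0.11) and with those under an estimated correlation (0.79). Both sets turned under the block in the treatment comparison (0.77 for the higher and 0.95 for the lower set).

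Leaving out each library in turn gave 4188 to 4612 genes in the sort, 0 to 5 for genotype, 0 to 83 for treatment, 0 to 15 for Eomes-TKO against GFP− and 3060 to 4499 against GFP+, 3195 to 4424 for GFP+ and 1 to 21 for GFP− against control IgG, and 199 to 719 for the interaction. The Eomes log2 fold change ran in that order from 7.84 to 8.3, −2.81 to −2.33, 0.54 to 1.69, 0.51 to 1.66, −7.5 to −6.31, 5.24 to 5.54, −2.9 to −2.44 and −0.86 to 0.31, and that of Foxp3 from −1.66 to −1.23 in the sort and from 2 to 2.39 in Eomes-TKO against GFP+ cells. Called lists ran from 11 to 12, 3 to 5, 5 to 13, 8 to 15, 10 to 13, 11 to 13, 9 to 13 and 11 to 15. The adjusted p of the higher set ran from 0.44 to 0.99 in genotype, 0.00014 to 0.82 in treatment and 1.9e-64 to 1.1e-42 in the interaction, and that of the lower set from 0.33 to 0.98, 0.011 to 0.79 and 1.3e-44 to 1.3e-33. The sets were chosen in the GFP+ libraries that the interaction also holds, so its values for them test nothing. Without treated Eomes-TKO replicate 1, the cytotoxic (adjusted p = 0.078) and T-box (0.062) lists turned in treatment, against 4.1e-07 and 3.4e-07 without replicate 2, and the T-box call was lost without control replicate 2 (0.4). Against GFP− cells the oxidative phosphorylation (0.083) and T-box (0.25) lists turned without replicate 1, against 3.8e-06 and 1.3e-06 without replicate 2, and both were lost without GFP− replicate 2 (0.21 and 0.13), as was the first without GFP− replicate 3 (0.12). Where an arm was left with 1 library, that library was assumed to vary like the other groups. Depth limits genes under about 0.468 CPM, the level of 3 counts in the shallowest library.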

Other observations

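The tests of Igkc, of Gm33707 and of the fall of Eomes and Kcnc1 were chosen only after the results were seen, and the gene lists were planned.

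Several helper programmes were mixed in GFP+ against GFP− cells and were not called as lists by camera. Of 16 regulatory T cell genes 5 rose and 9 fell, the same counts as when adjusted over the list alone (median −1.21, adjusted p = 0.32). Ikzf2, which encodes Helios, rose by 3.05 ± 0.24 to 569 ± 45.4 CPM and Ctla4 by 1.35 ± 0.16, whereas Il2ra, the high-affinity interleukin-2 receptor chain, fell by 1.77. Among follicular helper genes 8 of 17 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.25), with Cxcr5 at 306 ± 45.0 against 18.2 ± 4.19 CPM while their master regulator Bcl6 was at 40.1 ± 4.05 against 36.5 ± 4.87 CPM. Of 5 Th2 genes 2 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.45), and fry, against no change, called this list lower (adjusted p = 0.0074). Ccr8 (1.71 ± 0.40) and Ccr4 (1.46 ± 0.29) were higher and Gata3 (−0.67 ± 0.11), Il1rl1 (−4.00 ± 0.69) and Il17rb (−5.53 ± 0.70) lower. Costimulatory genes of the tumour necrosis factor receptor and CD28 families were divided at 6 and 6 of 17 (7 and 7 adjusted over the list alone; median 0.37, mean −0.09, test direction down, adjusted p = 0.84), with Icos up by 0.60 ± 0.15 and Cd40lg, the helper signal to B cells, down at 11.1 ± 1.23 against 67.5 ± 9.94 CPM. Glycolysis rose in 10 of 20 genes and fell in 1 (adjusted p = 0.19; 10 and 1 adjusted over the list alone) and nuclear oxidative phosphorylation genes in 1 of 33 (adjusted p = 0.55; 0 adjusted over the list alone).

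GFP− cells after 4-1BB antibody, compared with undivided cells after control IgG, also differed in single genes chosen after their values were seen. Bhlhe40, a factor of activated helper cells, rose by 2.07, Nr4a2 by 1.49 ± 0.19, the AP-1 subunit Junb by 1.00 and Irf1 by 0.68. Egr2 (22 ± 6.83 against 31 ± 1.73 CPM) and Egr3 (34.6 ± 6.5 against 46.7 ± 2.91 CPM) lay the other way without a call. The immediate early list rose in 2 of 23 members (3 adjusted over the list alone; median 0.15, adjusted p = 0.039, adjusted p = 0.61 with an estimated correlation), and its call was lost without GFP− replicate 2 or 3 (0.19 and 0.1) or control replicate 2 (0.28). Klrb1c, which encodes the NK1.1 antigen targeted by the depleting antibody, fell by 2.22 from 6.83 ± 0.239 to 1.49 ± 0.599 CPM (adjusted p = 0.0213). Without control replicate 2, none of the 5 genes that rose or fell here was called. Checkpoint genes rose in 3 of 20 and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.039, adjusted p = 0.7 with an estimated correlation; adjusted p = 0.21 without GFP− replicate 2 and 0.14 without control replicate 2).

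Igkc counts were high in the GFP+ libraries, at 76.1, 82.0 and 79.6 CPM, against 7.34 and 15.6 CPM in treated Eomes-TKO libraries and at most 1.67 CPM elsewhere. RNA from B cells, plasma cells or myeloma cells is argued against by the variable segments, with 0.1 Igkv counts per 100 Igkc counts in GFP+ libraries (2 to 1916; exact 95% Poisson interval 0.013 to 0.377) against 30.46 per 100 in treated Eomes-TKO libraries (60 to 197; 23 to 39.2), and by 6 Jchain and 0 Ighg or Igha counts against 61 and 300. Igkc sequence read out at a fixed rate with the Eomes reporter allele stays open: the GFP+ ratio of 12.1 Igkc per 100 Eomes counts predicts 8.3 counts in the GFP− libraries, where 9 were seen, and 34 in the control-treated Eomes-GFP libraries, where 15 were seen, 12 of them in replicate 2, which also held 9 Igkv and 5 Jchain counts (replicate 1 held 3 where 13.3 were predicted). Over these 5 libraries the log2 ratio of observed to predicted counts averaged −0.57 (95% t interval −2 to 0.87, with 0.5 added to each count). Transcription of the unrearranged kappa constant region in Eomes-rich cells may also be the source and was not tested.

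Gm33707 had 73 to 147 counts in the 5 Eomes-TKO libraries and 0 in the 8 Eomes-GFP libraries, at least 292-fold more against a floor of 3 counts over the 8 (0.043 CPM). Reads of the similar gene Eno1 misassigned at a fixed rate are argued against, since they predict 863 counts in the Eomes-GFP libraries. Gm33707 lies on chromosome 3 and Eomes on chromosome 9 in GENCODE M21 (GRCm38), so a variant at that reference position would not be next to the targeted gene. The reference position cannot show where the counted reads arose in the Eomes-TKO line, so a variant next to Eomes is not decided by it. A strain variant or a further engineered allele in the Eomes-TKO line cannot be told apart from the genotype, because the lowest of the 5 Eomes-TKO libraries still held 73 counts. Closer to Eomes, 3.2 Mb away, Stt3b stood at 305 ± 15.9 CPM in Eomes-TKO libraries (SD, n = 5; 287 to 325) against 77.9 to 209 CPM in Eomes-GFP libraries, and of 142 tested genes within 10 Mb of Eomes 9 had an unadjusted p under 0.05 between the control groups (6.3% against 3% elsewhere, Fisher's exact p = 0.042, with 0.29 within 5 Mb and 0.2 within 20 Mb).

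Eomes and Kcnc1 were lower in control-treated Eomes-TKO than Eomes-GFP cells, by −2.64 and −2.86 log2 units. A loss of cells with the profile of treated GFP+ cells is argued against: over 35 genes that stand apart in GFP+ cells, the median share of the GFP+ level lost was 0.1% (quartiles −0.29 and 0.51), against 1.98% for Eomes and 22.5% for Kcnc1. Of these genes 5 lay above 0.5 of the Eomes share, and Myb, outside the 35, was at 16.1%, so a loss of cells sharing part of that profile stays open. A loss of innate-like T cells as large as the Kcnc1 fall is argued against by their marker Zbtb16, with a log2 fold change of 0.07 (95% interval −0.81 to 0.95). That interval leaves a smaller loss open, and Zbtb16 cannot show a loss limited to an Eomes-expressing minority of them. The altered Eomes gene may itself give fewer Eomes reads in Eomes-TKO mice with no cell lost. The Eomes share would then not measure lost cells. This, a loss of Eomes-expressing cells of another profile, or an effect of Eomes on Kcnc1 within cells may account for the falls. None of these was tested, and genotype and any batch of the animals are confounded here.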
